A study of Mus musculus with 6 samples.

How the data were processed

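The series holds 6 single-cell RNA libraries of mouse brain leukocytes, 1 for each combination of 2 genotypes and 3 times. Per the labels, mice had the filament model of transient occlusion of the middle cerebral artery, with 60 min of occlusion followed by reperfusion, or were naive. The series design calls the earliest time 0 h after reperfusion, and the sample titles call those mice naive; the titles were followed. The genotypes were Cd300a-fl/fl (called fl/fl) and Cd300a-fl/fl with Cre recombinase at the Lyz2 locus (called Lyz2-cre), on a C57BL/6 background. Brains were perfused, homogenised, passed over a Percoll gradient and sorted for living CD45-positive cells, with 3 brains pooled per library and a stated viability above 85%. Each library is therefore 1 pool, and no combination of genotype and time has a second library.

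Per the submitters' processing notes, the authors made the files with Cell Ranger 3.0.2 and genome build mm10. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, whole numbers with no normalization, in filtered matrices. Per the labels' protocols the chemistry reads the polyadenylated end of transcripts, so a UMI does not show which exons a transcript holds. The exons flanked by loxP sites are not given in the sources used here.

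Scripts used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Barcodes with at least 300 genes and at most 10% mitochondrial UMIs were kept, which left 50634 of 51005. The authors' sources used here state no cell count. The automatic threshold of Scrublet, run through scanpy, called only 371 barcodes and was not used. Barcodes were ranked by its doublet score instead, and the highest-scoring 0.8% per 1000 barcodes in the deposited matrix were removed in each library. This took out 3531 barcodes and left 47103 cells, between 6721 and 9622 per library.

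Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes and 30 principal components were used, and Leiden clustering with 15 neighbours at resolution 1 gave 23 clusters. Libraries were not batch-corrected. Clusters were named from marker genes fixed before the data were examined. A cluster took the class with the highest marker score if at least 3 of its markers were seen in at least 10% of its cells and no other class had more markers among its top 10 genes by fold. The need for an own marker in the top 10 was dropped after the clusters were seen, folds were then taken against cells of other classes, and 1 macrophage cluster that also held dendritic cell markers was clustered again into 7 parts. Of these parts only those named border-associated macrophage or conventional dendritic cell kept a name. A part of 121 cells that met the rule for microglia and 1 of 9 cells that met it for T cells stayed unnamed. A further rule against clusters with few UMIs and no own marker in the top 10 left out none. The naming gave 12 microglia-like clusters. Those without an own marker in the top 10 were led by stress or chemokine genes or by Dst, Tanc2 and Csmd3. Cells left unnamed made up 2.38% and 2.64% of the fl/fl and Lyz2-cre naive libraries, 0.522% and 3.26% at 1 h, and 0.429% and 0.395% at 3 h. Class names rest on these markers alone and are written with the ending -like.

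Raw UMI counts were summed per library and class, and cells were never used as replicates. Microglia-like, monocyte-like and neutrophil-like sums were tested with edgeR's quasi-likelihood test (robust fit, TMM factors, filterByExpr) and Benjamini-Hochberg adjustment at 0.05, in a model with genotype and time. That model has 2 residual degrees of freedom. Times are compared across 2 libraries each and genotypes across 3 libraries each, and any difference of the time course between genotypes stays in the residual. All adjusted p-values below come from this test unless another tool is named. Libraries of the other genotype or other times act as replicates, and no group has a second pool. So p-values rest on departures from the additive model, where spread between pools and any genotype-by-time difference are mixed. The fit also borrows spread across genes. Its median prior degrees of freedom were 7.64 in microglia-like, 10.1 in monocyte-like and 10.3 in neutrophil-like cells. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Border-associated macrophage-like cells were too few to test, since the plan asked for at least 20 cells in every library and 3 libraries held 15 or 17. A single library against another got no test. Levels are in CPM, the UMIs of a gene scaled by all UMIs of its class in that library, with exact Poisson intervals, and shares have exact Clopper-Pearson intervals, both at 95% and both covering counting error only. A count of 0 was given a floor of 3 UMIs.

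Named genes followed a rule fixed before the data were examined. Cd300a and Lyz2 were always eligible. For each contrast the rule gives the genes past the threshold with the same sign in every library pair and a mean of at least 20 CPM in the higher group, up to 10 per direction by fold in microglia-like cells and 5 in the other classes. It leaves out sex-linked, mitochondrial, ribosomal, haemoglobin and antigen receptor genes and predicted models. Where fewer than 3 pass, the 3 largest others are eligible as not passing. From each list with 3 or more genes past the threshold it gives the 4 members with the largest fold. The subset of these named below was chosen after the values were seen. Cd83, Cxcl16, Dnaja1, Dnajb1, Egr2, Hspa8 and Nfkbiz in the microglia-like genotype comparison and Gprc5c in the monocyte-like one lie outside the rule and were named after their values were seen. For single genotype comparisons at 1 time it gives the 5 largest ratios per direction among genes of at least 50 CPM whose intervals do not overlap.

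The 18 gene lists were also fixed beforehand: homeostatic microglia, immediate early and dissociation response, heat shock and chaperone, NF-kB and inflammatory cytokine, chemokine, type I interferon response, hypoxia and glycolysis, unfolded protein and integrated stress response, phagocytosis and apoptotic cell uptake, disease-associated microglia, CD300 family, Toll-like receptor and alarmin signalling, MHC class II, MHC class I, cell cycle, leukocyte adhesion and migration, anti-inflammatory and repair, and sex-linked genes. In microglia-like cells lists were tested with camera in edgeR at a preset correlation of 0.01, with an estimated correlation as the alternative, and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes.

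The test was checked on simulated counts with 200 genes changed. In microglia-like cells, over 12814 genes, 79% of the genes changed by 1 on the log2 scale were recovered for 3 h against naive and 84% for genotype. Over 8931 genes in monocyte-like cells these were 58% and 86%. Over 7713 genes in neutrophil-like cells they were 22% and 20%, so neutrophil-like counts of changed genes miss most changes of that size. Of genes changed by 0.5, 49% and 61% were recovered in microglia-like, 8% and 28% in monocyte-like and 1% and 1% in neutrophil-like cells. False calls numbered 9 and 8, 4 and 14, and 5 and 2. The 14 for genotype in monocyte-like cells arose beside 200 changed genes, and false calls can grow with the number of calls. They therefore cannot be set against the 4 genes called there in the data, and no simulation without changed genes was run. Median shifts of all genes were under 0.1 on the log2 scale under both scalings tried.

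Alternatives fixed beforehand were DESeq2 in place of edgeR, DESeq2 size factors in place of TMM, other filters on counts and cells, doublets kept, equal cell numbers, thinned counts, another clustering resolution, a model without the other factor, and each library left out in turn. Coordinates are from GENCODE vM21 on GRCm38, the assembly that mm10 names.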

Results

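Gene expression was measured in single living CD45-positive leukocytes sorted from mouse brain, in naive mice and at 1 h and 3 h after reperfusion of a middle cerebral artery that had been occluded for 60 min. CD300a is an inhibitory receptor for phosphatidylserine, a lipid exposed on dying cells, and the fl/fl mice are compared with Lyz2-cre mice, in which Cre recombinase is meant to delete its gene in myeloid cells. There were 6 libraries, 1 per genotype and time, each a pool of 3 brains. Total counts ran from 35479437 UMIs in the fl/fl 3 h library to 48478866 in the Lyz2-cre 3 h library, and the median cell held between 3985 and 5256 UMIs. After filtering, 47103 cells were used.

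Microglia-like cells, the resident macrophages of the brain, were the largest class in all 6 libraries, at 70.2% to 87.7% of cells. In fl/fl mice their share was 82.7% in naive brain, 87.7% at 1 h and 70.2% at 3 h. In Lyz2-cre mice it was 81.8%, 76.8% and 76.1%. Neutrophil-like cells made up 2.26%, 4.08% and 15.6% of the fl/fl libraries and 4.32%, 10.3% and 10.4% of the Lyz2-cre libraries at the same times. Monocyte-like cells were at 1.68%, 2.20% and 7.54% in fl/fl and 3.59%, 3.60% and 8.45% in Lyz2-cre mice. T-cell-like cells were at 7.34% and 3.07% of the naive libraries and between 0.973% and 2.25% of the others, and under the stricter cell filter at 3.95% and 1.40% of the naive libraries and between 0.380% and 1.503% of the others. In both genotypes the 95% Clopper-Pearson intervals of the neutrophil-like and monocyte-like shares at 3 h lay above those of the naive libraries. There is no replicate for any share, the intervals cover counting error only, and the CD45 sort, the gradient and the perfusion set which cells could be counted. Under the stricter filter the 1 h neutrophil-like shares were 2.83% and 8.66%, and the microglia-like shares ran from 73.2% to 91.5%.

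**Figure D1:**
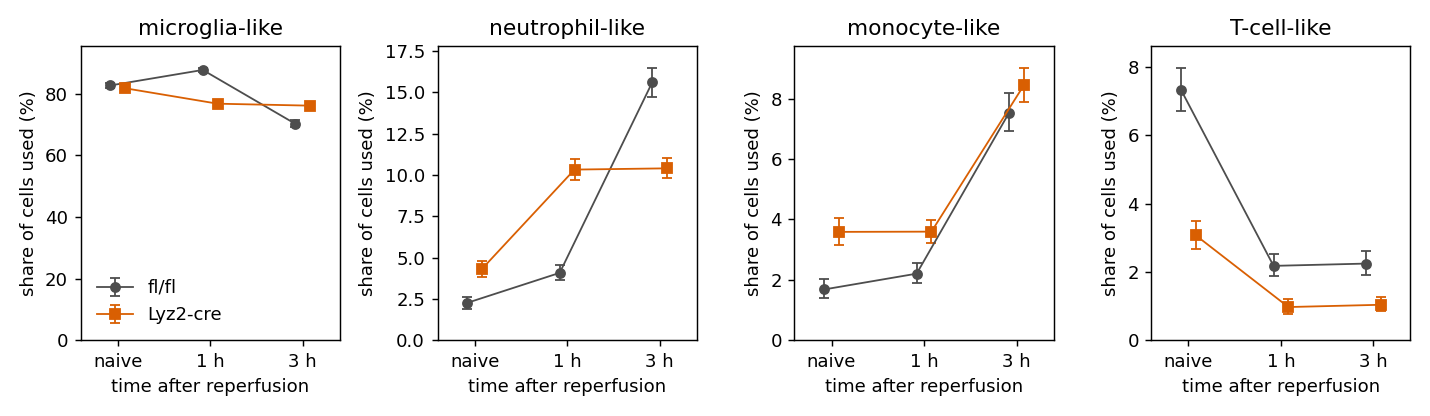
Share of the cells used (%, y axis from 0) that were microglia-like, neutrophil-like, monocyte-like or T-cell-like, by time after reperfusion, with 1 point per library, grey circles for fl/fl and orange squares for Lyz2-cre. Bars are exact 95% Clopper-Pearson intervals. The neutrophil-like share reaches 15.6% in the fl/fl and 10.4% in the Lyz2-cre 3 h library.

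The targeted gene was looked at first. Cd300a (ENSMUSG00000034652) lies on chromosome 11 from 114890041 to 114904654 on the plus strand of GRCm38 and has 7 exons in its first annotated transcript. In neutrophil-like cells its level was 179, 256 and 128 CPM in the naive, 1 h and 3 h fl/fl libraries and 16.3, 11.2 and 9.83 CPM in the Lyz2-cre libraries, a fall of 3.78 ± 0.24 (SE) on the log2 scale (adjusted p = 1.51e-05). In monocyte-like cells it was 457, 444 and 180 CPM against 225, 189 and 87.9 CPM, which fell by 1.11 ± 0.11 (adjusted p = 0.0029). In microglia-like cells it was 172, 212 and 206 CPM against 137, 171 and 163 CPM and fell by 0.38 ± 0.06 (adjusted p = 0.0358). In conventional dendritic cell-like cells, which were not tested, it was 160, 163 and 180 CPM in fl/fl and 202, 200 and 232 CPM in Lyz2-cre mice. B-cell-like cells, a lymphoid class, held 2.39 to 16.6 CPM over the 6 libraries. Because UMIs come from the polyadenylated end of transcripts and the deleted exons are not given in the sources used here, transcripts that lack those exons could still be counted, so the levels do not measure how often the gene was deleted. In microglia-like cells the Cd300a difference lost its call when any 1 of the naive or 1 h libraries was left out.

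Lyz2 (ENSMUSG00000069516), the lysozyme gene that carries the Cre insertion, lies on chromosome 10 from 117277331 to 117282321 on the minus strand, with 4 exons. In monocyte-like cells it was 25210, 24047 and 19538 CPM in the fl/fl libraries and 29.0, 98.4 and 26.9 CPM in the Lyz2-cre libraries. In neutrophil-like cells it was 12963, 6321 and 2450 CPM against 49.0, 80.2 and 17.8 CPM (log2 fold change -6.97 ± 0.42, adjusted p = 2.89e-05). In microglia-like cells it was 210, 217 and 195 CPM against 0.328, 0.623 and 0.646 CPM (log2 fold change -8.65 ± 0.14, adjusted p = 1.47e-09). The monocyte-like difference of -9.03 ± 0.71 on the log2 scale was not called (adjusted p = 0.738 in edgeR), and it was called with DESeq2 and without either 1 h library. In each of these 3 classes Lyz2 was lower in every library labelled Lyz2-cre than in every library labelled fl/fl. Its neighbour Lyz1, on chromosome 10 from 117287797 to 117292868, is a near-identical copy whose counts may be shared with those of Lyz2, so its values are uncertain. In monocyte-like cells Lyz1 was 66.3, 38.8 and 8.49 CPM in fl/fl and 676, 460 and 483 CPM in Lyz2-cre mice (log2 fold change 4.26 ± 0.70, adjusted p = 0.975, not called by edgeR, called by DESeq2 and without either 3 h library).

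**Figure D2:**
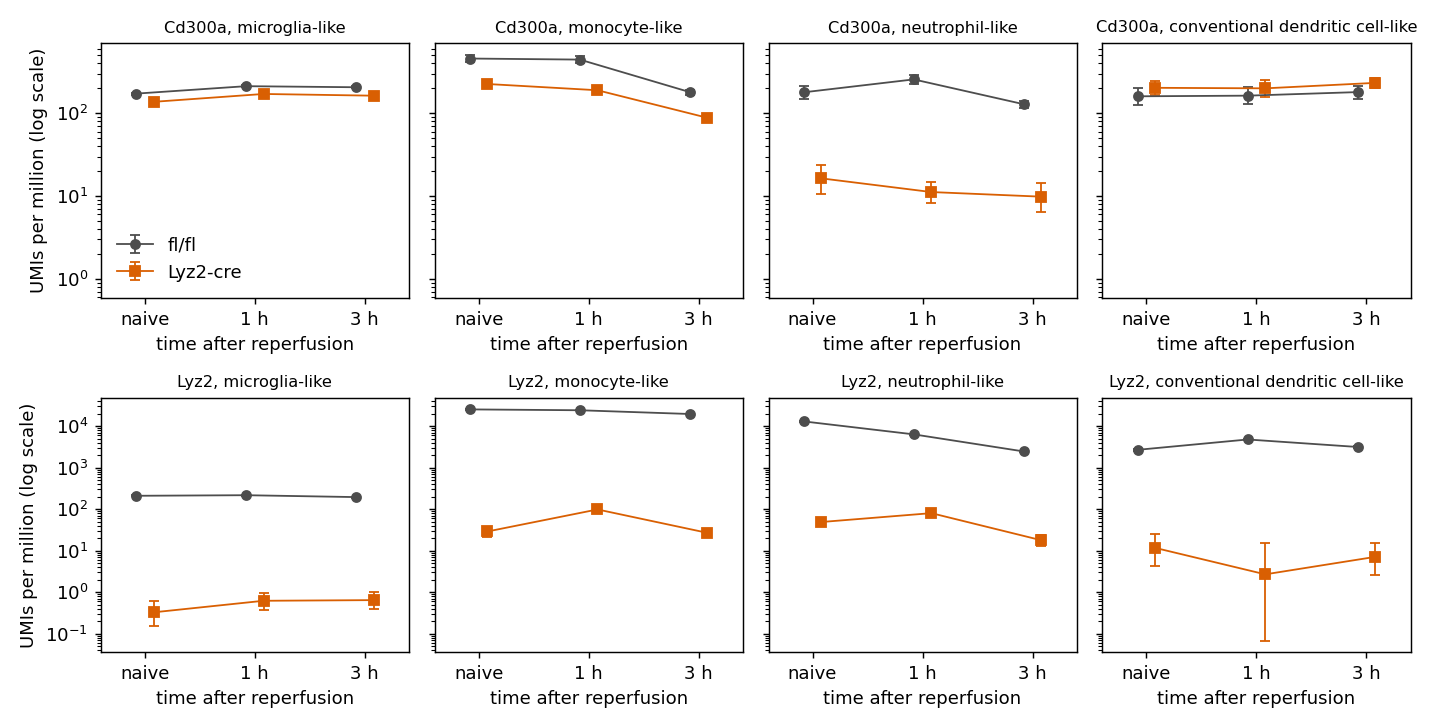
Cd300a (top) and Lyz2 (bottom) in CPM of 4 classes, on log axes, by time after reperfusion, with 1 point per library, grey circles for fl/fl and orange squares for Lyz2-cre. Bars are exact 95% Poisson intervals of the counts. In neutrophil-like cells Cd300a lies between 128 and 256 CPM in fl/fl and between 9.83 and 16.3 CPM in Lyz2-cre libraries.

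The first comparison asked how microglia-like cells differed at 1 h after reperfusion from naive brain, over both genotypes. The inducible chaperone gene Hspa1b went from 3.04 and 2.13 CPM in the naive libraries to 1137 and 588 CPM (log2 fold change 8.45 ± 0.15, n = 2 libraries per time, adjusted p = 1.9e-09), and Hspa1a rose by 5.14 ± 0.30. Gdf15, a stress-induced cytokine, rose by 5.79 ± 0.54 on the log2 scale, Rcan1, a calcineurin regulator, by 4.19 ± 0.30, and Cd83, an activation marker, by 2.92 ± 0.11. Fosb and Egr1, transcription factors of the immediate early response, fell by 2.84 ± 0.12 and 1.92 ± 0.10, and Nfkbiz, a regulator of NF-kB targets, fell by 2.48 ± 0.09. In all, 3448 of 12814 genes tested changed, 1811 up and 1637 down. The microglia-like cells came mostly from clusters 2 and 10 in naive libraries and from clusters 0 and 12 at 1 h.

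Of the 20 measured genes of the immediate early and dissociation response list, 1 rose and 17 fell at 1 h, and the counts adjusted over the list alone were also 1 and 17. Nr4a1 rose by 2.72 ± 0.09, while Fosb, Egr1 and Egr3 fell, Egr3 by 1.76 ± 0.08. The list was called by camera, with adjusted p = 0.198 with an estimated correlation. Of 21 NF-kB and inflammatory cytokine genes 7 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.200 with an estimated correlation). Of 15 heat shock and chaperone genes 6 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.215 with an estimated correlation). Hsph1 rose by 1.82 ± 0.28 and Dnajb1, a partner of Hsp70 proteins, fell by 1.39 ± 0.08. Of 20 hypoxia and glycolysis genes 12 rose and none fell (13 adjusted over the list alone; adjusted p = 0.265 with an estimated correlation), among them the glucose transporter Slc2a1 at 1.32 ± 0.10 and the mTOR inhibitor Ddit4 at 3.72 ± 0.51. Of 17 disease-associated microglia genes 11 rose and none fell (12 adjusted over the list alone; adjusted p = 0.198 with an estimated correlation), with the growth factor Csf1 at 2.51 ± 0.23 and the lipid carrier Fabp5 at 2.28 ± 0.27. Of 13 chemokine genes 8 rose and 1 fell (8 and 2 adjusted over the list alone; adjusted p = 0.215 with an estimated correlation), with Ccl4 up by 1.51 ± 0.13 and Ccl12 down, at -1.53 ± 0.22. Of 16 homeostatic genes, most of which also named the class, 9 rose and 3 fell (9 and 3 adjusted over the list alone; adjusted p = 0.563 with an estimated correlation). Fcrls rose by 0.73 ± 0.09 and the fractalkine receptor Cx3cr1 fell by 0.56 ± 0.09. Cd300a itself rose by 0.41 ± 0.08 (adjusted p = 0.00489). The neutrophil transcripts S100a8 and S100a9 were at 87.6 and 147 CPM in the microglia-like cells of the Lyz2-cre 1 h library and at 9.05 and 16.5 CPM in those of the fl/fl 1 h library.

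With 2 residual degrees of freedom the counts depend on single libraries: 853, 849, 832 and 831 genes changed at 1 h when the fl/fl naive, Lyz2-cre naive, fl/fl 1 h or Lyz2-cre 1 h library was left out, and DESeq2 called 2099. Hspa1a, Hsph1, Gdf15, Rcan1, Ddit4 and Csf1 lost their call without either 3 h library, Cx3cr1 and Cd300a without either naive library, Fcrls and Fabp5 without the fl/fl naive library, and Ccl12 and Cd300a without either 1 h library.

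**Figure D3:**
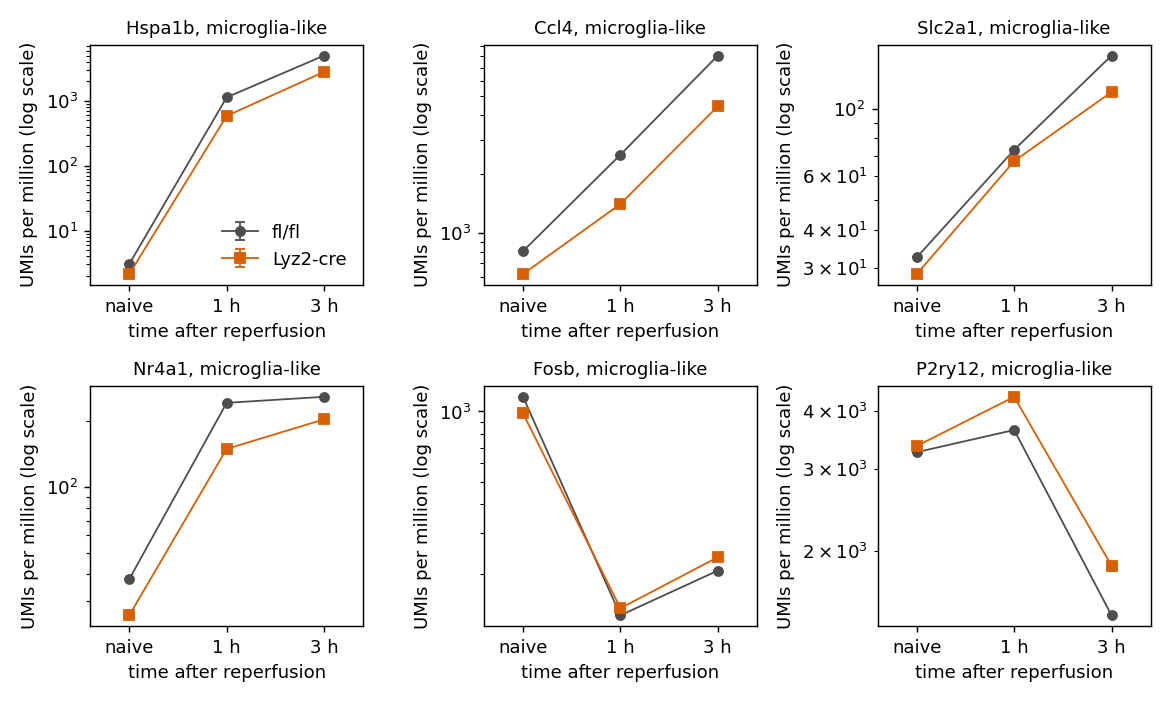
Level of 6 genes in microglia-like cells, in CPM on log axes, by time after reperfusion, with 1 point per library, grey circles and lines for fl/fl and orange squares and lines for Lyz2-cre. Hspa1b, Ccl4, Slc2a1 and Nr4a1 are higher and Fosb is lower at 1 h and 3 h than in naive libraries, and P2ry12 is lower at 3 h, at 1458 and 1862 CPM against 3261 and 3362 CPM.

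At 3 h after reperfusion microglia-like cells held far more chaperone, cytokine and chemokine transcripts than in naive brain and fewer homeostatic ones. Hspa1b reached 5021 and 2810 CPM (log2 fold change 10.62 ± 0.16, n = 2, adjusted p = 3.77e-10). The neutrophil attractant Cxcl2 rose by 8.05 ± 0.28, from 0.465 and 0.558 CPM to 138 and 121 CPM, and Ccl4 by 3.16 ± 0.14, to 8079 and 4449 CPM. Ptgs2, which makes prostaglandin precursors, rose by 5.81 ± 0.16. The purinergic receptor P2ry12 fell by 0.93 ± 0.10 (adjusted p = 0.000132). In all, 6124 of 12814 genes changed, 3138 up and 2986 down. Markers of other classes moved in these cells too. Monocyte markers summed to 111 and 106 CPM in naive libraries, 333 and 254 CPM at 1 h and 356 and 340 CPM at 3 h, and border-associated macrophage markers to 166 and 207, 320 and 302, and 397 and 435 CPM. The monocyte markers include Nr4a1, which is also in the immediate early list and rose in microglia-like cells at both times. Their sum therefore does not by itself show transcripts of monocytes. Cxcl2, Il1b, Il1rn and Cd300lf also rose in monocyte-like cells, and how much of their rise here came from such cells was not tested. At 3 h most microglia-like cells came from clusters 11, 0, 4, 8 and 13 in fl/fl and from clusters 3, 8, 13 and 0 in Lyz2-cre mice.

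Among the lists, 14 of 15 heat shock and chaperone genes rose at 3 h and none fell (14 adjusted over the list alone; adjusted p = 0.160 with an estimated correlation). Hspa1a rose by 7.80 ± 0.33. Of 21 NF-kB and inflammatory cytokine genes 18 rose and 1 fell (18 and 1 adjusted over the list alone; adjusted p = 0.160 with an estimated correlation), with the interleukin-1 receptor antagonist Il1rn at 6.01 ± 0.36 and Il1b at 4.28 ± 0.59. Of 13 chemokine genes 9 rose and none fell (10 adjusted over the list alone; adjusted p = 0.160 with an estimated correlation), with Cxcl10 at 2.99 ± 0.44. Of 16 homeostatic genes 1 rose and 12 fell (1 and 12 adjusted over the list alone; adjusted p = 0.277 with an estimated correlation), with Gpr34 at -0.79 ± 0.10, Cx3cr1 at -0.77 ± 0.09 and Olfml3 at -0.75 ± 0.09. Of 20 hypoxia and glycolysis genes 15 rose and none fell (15 adjusted over the list alone; adjusted p = 0.296 with an estimated correlation), with Slc2a1 at 2.19 ± 0.10. Of 20 immediate early genes 4 rose and 12 fell (4 and 13 adjusted over the list alone; adjusted p = 0.277 with an estimated correlation), with Nr4a1 at 2.97 ± 0.09 and Fosb and Klf2 at -2.19 ± 0.11 and -1.62 ± 0.27. Of 6 measured CD300 family genes 4 rose and none fell (4 adjusted over the list alone; adjusted p = 0.258 with an estimated correlation): Cd300lf, a family member that like Cd300a binds phosphatidylserine, rose by 6.30 ± 0.43 from 1.75 and 1.28 CPM to 109 and 111 CPM, Cd300lb by 2.60 ± 0.33 and Cd300a by 0.33 ± 0.08.

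The other lists at 3 h gave these counts. Of 11 anti-inflammatory and repair genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.160 with an estimated correlation), with the haem oxygenase Hmox1 at 4.10 ± 0.18. Of 17 disease-associated microglia genes 9 rose and none fell (10 and 1 adjusted over the list alone; adjusted p = 0.200 with an estimated correlation). Of 24 phagocytosis genes 7 rose and 2 fell (7 and 2 adjusted over the list alone; adjusted p = 0.277 with an estimated correlation), with the scavenger receptor Msr1 at 3.02 ± 0.18. Of 13 unfolded protein and integrated stress response genes 7 rose and none fell (7 adjusted over the list alone; adjusted p = 0.277 with an estimated correlation). Of 22 Toll-like receptor and alarmin genes 9 rose and 1 fell (9 and 2 adjusted over the list alone; adjusted p = 0.277 with an estimated correlation), with Tlr2 at 1.37 ± 0.09. Of 16 leukocyte adhesion and migration genes 8 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.340 with an estimated correlation), with the chemokine receptor Cxcr4 at 3.90 ± 0.32. Lists not called by camera were type I interferon response (1 up and 1 down of 18), MHC class II (2 up and 1 down of 11), MHC class I (2 up and 3 down of 11), cell cycle (3 up and 2 down of 14) and sex-linked genes (2 up of 5), with the same counts adjusted over the list alone. Without the fl/fl naive library 2867 genes changed at 3 h. Hspa1a, Il1b, Cxcl10 and Klf2 lost their call without either 3 h library, and Cd300a without either naive library.

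Between 1 h and 3 h, 6099 of 12814 genes changed in microglia-like cells, 3256 up and 2843 down. Cxcl2 rose by 5.12 ± 0.22 (n = 2 libraries per time, adjusted p = 5.29e-05), Srxn1 and Slc7a11, which serve the defence against oxidants, by 4.60 ± 0.46 and 3.58 ± 0.11, and Ptgs2 by 3.60 ± 0.13. Gal3st4, a sulfotransferase, and Slc46a1, a folate transporter, fell by 1.91 ± 0.11 and 1.86 ± 0.09. Of 16 homeostatic genes none rose and 12 fell (12 adjusted over the list alone; adjusted p = 0.279 with an estimated correlation), with P2ry12 at -1.29 ± 0.10, Olfml3 at -1.30 ± 0.10 and the growth factor receptor Csf1r at -1.02 ± 0.09. Of 20 immediate early genes 13 rose and none fell (14 adjusted over the list alone; adjusted p = 0.279 with an estimated correlation), with Atf3 at 1.92 ± 0.14, Egr1 at 1.30 ± 0.10 and Klf6 at 1.27 ± 0.10. Of 15 heat shock genes 14 rose (14 adjusted over the list alone; adjusted p = 0.279 with an estimated correlation), with Hsp90aa1 at 2.82 ± 0.21. Of 21 NF-kB genes 15 rose and none fell (15 adjusted over the list alone; adjusted p = 0.234 with an estimated correlation), with Il1rn at 4.73 ± 0.31. Of 11 MHC class I genes 1 rose and 5 fell (1 and 5 adjusted over the list alone), and camera did not call the list; Nlrc5, a regulator of such genes, rose by 2.57 ± 0.22. Without the fl/fl 1 h or the Lyz2-cre 1 h library 3259 and 3017 genes changed.

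The genotype comparison asked whether microglia-like cells of Lyz2-cre mice differed from those of fl/fl mice over the 3 times. The 54 genes that fell in Lyz2-cre mice included Lyz2, Cd300a and 4 chemokine, 4 chaperone and 4 immediate early genes. The inflammatory chemokine genes Ccl3 and Ccl4 fell by 0.77 ± 0.09 and 0.75 ± 0.10 (n = 3 libraries per genotype, adjusted p = 0.00996 and adjusted p = 0.0197). At 3 h Ccl3 was at 5847 CPM in fl/fl and 3100 CPM in Lyz2-cre mice. Hspa1b fell by 0.90 ± 0.09, the transcription factor Maff by 1.17 ± 0.11, the kinase Pim1 by 0.89 ± 0.07 and the nuclear RNA Neat1 by 0.71 ± 0.07. Klhdc8b rose by 0.44 ± 0.07. In all, 61 of 12814 genes changed, 7 up and 54 down, against 1357 at an unadjusted p under 0.05. The cells of the class also lay in different clusters by genotype. Cluster 4, led by Hspa1a and Hspa1b, held 3.56% of the class in fl/fl and 0.313% in Lyz2-cre mice at 1 h and 14.1% and 6.94% at 3 h. Cluster 11, with Ccl3 and Ccl4 among its top genes, held 24.7% and 10.5% at 3 h, and cluster 3, led by Sox4, Hspa1a and Hspa1b, 7.28% and 23.2%. Clusters were formed on such genes, so these shares are not separate evidence, and whether cells changed or the mix of cells did is not settled by the summed counts.

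Of 15 heat shock and chaperone genes none rose and 4 fell with genotype (14 fell adjusted over the list alone; adjusted p = 0.225 with an estimated correlation). These were Hspa1b, Dnajb1, Hspa8 and Dnaja1, the last 3 at -0.60 ± 0.07, -0.52 ± 0.08 and -0.54 ± 0.08, while Hsph1 was at -1.23 ± 0.22 without passing in edgeR and passed in DESeq2 and without the Lyz2-cre 1 h library. Of 20 immediate early genes 4 fell (12 adjusted over the list alone; adjusted p = 0.221 with an estimated correlation): Socs3, Egr3, Nr4a1 and Egr2, at -0.72 ± 0.10, -0.66 ± 0.07, -0.59 ± 0.07 and -0.52 ± 0.08. Of 21 NF-kB genes 3 fell (13 adjusted over the list alone; adjusted p = 0.168 with an estimated correlation): Ptgs2, Nfkbiz and Cd83, at -0.96 ± 0.12, -0.48 ± 0.07 and -0.48 ± 0.08. Of 13 chemokine genes 4 fell (1 up and 5 down adjusted over the list alone; adjusted p = 0.221 with an estimated correlation), Ccl5 by 1.18 ± 0.14 and Cxcl16 by 0.36 ± 0.06 beside Ccl3 and Ccl4. Dnajb1, Dnaja1, Hspa8, Egr2, Nfkbiz, Cd83 and Cxcl16 were named after their values were seen. Of 18 type I interferon response genes none passed (1 fell adjusted over the list alone), and the list was called by camera, with adjusted p = 0.302 with an estimated correlation. It was not called by fry (adjusted p = 0.341). No gene of the homeostatic, hypoxia or phagocytosis lists passed, by edgeR, of 16, 20 and 24 measured, and of these lists camera called the homeostatic one, upward (adjusted p = 0.323 with an estimated correlation). The S100a8 and S100a9 levels given for the Lyz2-cre 1 h library stand beside these groups too.

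The genotype calls rest on few degrees of freedom. Since the model holds time, leaving out either library of a time takes the whole time out of the genotype contrast. It also leaves fewer residual degrees of freedom. The 2 libraries of a time therefore give nearly the same test, and calls lost without either are not separate losses. There were 11, 11 and 18 calls without the fl/fl naive, Lyz2-cre naive or fl/fl 1 h library, 189 and 210 without the fl/fl 3 h or Lyz2-cre 3 h library, 129 with DESeq2, 234 with no filter on low counts and 1 with time left out of the model. Of the genes named here as passing, Lyz2 and Pim1 passed with each library left out, Maff was lost without the fl/fl 1 h library, and the others were lost without 2 or more single libraries.

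In monocyte-like cells, blood-derived phagocytes, 210 of 8931 genes changed at 1 h, 125 up and 85 down. Genes of MHC class II antigen presentation fell and a glucocorticoid target, a matrix protein gene and a chemokine receptor gene rose. The class II regulator Ciita fell by 2.15 ± 0.37 on the log2 scale (n = 2 libraries per time, adjusted p = 0.0115) and H2-Ab1 by 1.84 ± 0.19, and 5 of 9 measured list members fell with none up (8 fell adjusted over the list alone). Fkbp5, a glucocorticoid target, rose by 3.86 ± 0.36, the matrix protein gene Thbs1 by 3.06 ± 0.20 and the chemokine receptor Ccr1 by 2.95 ± 0.36. Of 18 hypoxia and glycolysis genes 6 rose and none fell (9 adjusted over the list alone), with Slc2a1 at 1.70 ± 0.22 and Ddit4 at 1.52 ± 0.26. The lipase gene Lpl fell by 2.32 ± 0.24. Microglia markers summed to 3384 and 1839 CPM in the monocyte-like cells of the naive libraries and 1604 and 1943 CPM at 1 h, and neutrophil markers to 207 and 254 CPM and to 326 and 1997 CPM. The microglia markers include Cx3cr1, which is also high in patrolling monocytes, so their sum is not a measure of microglia transcripts alone. Without the fl/fl naive library 630 genes changed, with DESeq2 118, with doublets kept 137, and in the largest cluster of the class alone, an alternative chosen after the data were seen, 92.

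At 3 h, 2469 of 8931 genes changed in monocyte-like cells, 1295 up and 1174 down. Cd14, a co-receptor for bacterial lipopolysaccharide, rose by 3.85 ± 0.18 (n = 2, adjusted p = 1.16e-07), Cxcl2 by 4.74 ± 0.34, Ccr1 by 4.56 ± 0.36 and Il1b by 2.79 ± 0.35. The fractalkine receptor Cx3cr1, high in patrolling monocytes and in microglia, fell by 2.90 ± 0.17, and Cd300a fell by 1.16 ± 0.14, to 180 and 87.9 CPM. Of 18 hypoxia and glycolysis genes 11 rose and none fell (11 adjusted over the list alone), with Hif1a at 2.43 ± 0.17 and Slc2a1 at 2.82 ± 0.20. Of 14 heat shock genes 10 rose and none fell (10 adjusted over the list alone), with Hsph1 at 2.64 ± 0.25. Of 19 NF-kB genes 6 rose and 10 fell (6 and 10 adjusted over the list alone), with Il1rn at 2.83 ± 0.27 and Il1a at -2.71 ± 0.48. Of 7 CD300 family genes 1 rose and 5 fell (1 and 5 adjusted over the list alone): Cd300lf rose by 2.69 ± 0.22 and Cd300e fell by 1.76 ± 0.21. Of 11 MHC class I genes 7 fell (8 adjusted over the list alone), with H2-K1 at -0.89 ± 0.12. Of 24 phagocytosis genes 3 rose and 13 fell (3 and 15 adjusted over the list alone), with the complement gene C1qc at -2.02 ± 0.26. Of 16 homeostatic microglia genes 15 fell (16 adjusted over the list alone), and the microglia marker sum in monocyte-like cells was 491 and 463 CPM at 3 h. Both the list and the sum hold Cx3cr1, so they also depend on the mix of monocyte-like cells. Cluster 20, led by Ace and Ear2, held 55.8% and 68.9% of monocyte-like cells in the naive libraries, and cluster 21, with Saa3, Vcan and Ccr2 among its top genes, held 77.8% and 81.8% at 3 h. Neutrophil markers in the class summed to 3962 and 1833 CPM at 3 h and 207 and 254 CPM in naive libraries. Without the fl/fl 3 h or Lyz2-cre 3 h library 1301 and 1037 genes changed, with DESeq2 1268 and in the largest cluster alone 1519. Il1a and C1qc lost their call with doublets kept.

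Between genotypes 4 of 8931 genes changed in monocyte-like cells, against 382 at an unadjusted p under 0.05, and DESeq2 called 5. Those 382 are a smaller share of the genes tested than the 0.05 that such a threshold would pass with no effect. Cd300a fell as given above. Spp1, the gene of osteopontin, fell by 2.13 ± 0.24 (n = 3 libraries per genotype, adjusted p = 0.00561), at 125 CPM in fl/fl and 26.9 CPM in Lyz2-cre mice at 3 h and at or under 2.77 CPM in the other libraries. Lrg1, a gene of neutrophil granules and the acute phase, fell by 1.38 ± 0.21 (adjusted p = 0.0463), at 230 and 85.0 CPM at 3 h. Neutrophil markers in this class summed to 3962 and 1833 CPM at 3 h, with S100a9 at 1406 and 306 CPM, so neutrophil transcripts are not excluded as a source of the Lrg1 difference. At 1 h S100a9 was at 12.9 and 768 CPM and Lrg1 at 6.47 and 5.07 CPM. Gprc5c, an orphan receptor named after its values were seen, was at 2.41, 0 and 0.592 CPM in fl/fl and 27.4, 17.8 and 6.21 CPM in Lyz2-cre mice (adjusted p = 0.0129). Spp1 and Lrg1 lost their call without either 3 h library and with DESeq2, and Lrg1 also with doublets kept. The count was 65, 66, 46 and 44 without the fl/fl naive, Lyz2-cre naive, fl/fl 1 h or Lyz2-cre 1 h library and 9 without either 3 h library.

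In neutrophil-like cells 56 of 7713 genes changed at 1 h, all 56 up. Rabgef1, a regulator of endosome fusion, rose by 3.36 ± 0.39 on the log2 scale (n = 2 libraries per time, adjusted p = 0.00223), and the cell cycle inhibitor Cdkn1a by 3.38 ± 0.54. Hspa1b was at 1.55 and 0.629 CPM in the naive libraries and at 83.2 and 38.3 CPM at 1 h, and Hspa1a at 1.55 and 1.89 CPM and 85.3 and 30.9 CPM; both passed, and their naive levels rest on 1 to 3 UMIs. At 3 h 2204 genes changed, 1352 up and 852 down. Cd14 rose by 6.29 ± 0.55 (adjusted p = 8.13e-05), Slc2a1 by 4.72 ± 0.33, and Cxcl2 by 4.04 ± 0.31. Cebpe, a transcription factor of granule formation, fell by 2.96 ± 0.40 and Ear2 by 4.15 ± 0.47.

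Of 19 hypoxia and glycolysis genes 11 rose in neutrophil-like cells at 3 h and none fell (13 adjusted over the list alone), with the oxygen sensor Egln3 at 3.73 ± 0.37. Of 17 type I interferon response genes 9 rose and none fell (11 and 1 adjusted over the list alone), with Isg15 at 2.96 ± 0.26, Oasl2 at 2.10 ± 0.26 and Ifit1 at 2.04 ± 0.26. Of 20 immediate early genes 10 rose and none fell (11 adjusted over the list alone), with the cytokine signalling inhibitor Socs3 at 4.73 ± 0.54 and Ier3 at 4.48 ± 0.41. Of 19 NF-kB genes 13 rose and 1 fell (13 and 1 adjusted over the list alone), and of 19 Toll-like receptor genes 10 rose and 1 fell (11 and 1 adjusted over the list alone), with Tlr4 at 3.72 ± 0.30. Of 5 CD300 family genes 3 rose and none fell (3 adjusted over the list alone), with Cd300lf at 2.56 ± 0.29 and Cd300ld at 2.09 ± 0.34. The interleukin-4 receptor gene Il4ra rose by 3.98 ± 0.28. Cluster 16, which has the granule genes Ltf, Ngp and Lcn2 of immature neutrophils among its top genes, held 38.8% and 51.7% of neutrophil-like cells in the naive libraries, 14.7% and 48.6% at 1 h and 3.03% and 3.10% at 3 h, and cluster 17 held the rest. The microglia marker sum in the class was 3058 and 800 CPM in naive libraries, 3405 and 1859 CPM at 1 h and 401 and 642 CPM at 3 h. Without the fl/fl naive or Lyz2-cre naive library 776 and 881 genes changed at 3 h, with DESeq2 1333 and in the largest cluster alone 1078. At 1 h the count was 4 and 2 without those libraries, 162, 292, 260 and 273 without the fl/fl 1 h, Lyz2-cre 1 h, fl/fl 3 h or Lyz2-cre 3 h library, 100 with DESeq2 and 123 in the largest cluster alone. Cdkn1a and Rabgef1 lost their call without either naive library.

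Between genotypes Cd300a and Lyz2 were the 2 genes called in neutrophil-like cells, both lower in Lyz2-cre mice, against 397 genes at an unadjusted p under 0.05 and 3 called by DESeq2. Of 7713 genes tested, 397 is close to the share of 0.05 that such a threshold would pass with no effect. The count was 15 without either 1 h library and 95 and 94 without the fl/fl 3 h or Lyz2-cre 3 h library.

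Genotypes at a single time can be compared only as values of 1 library each. In microglia-like cells at 3 h the MHC class II genes H2-Aa and H2-Eb1 were at 71.5 and 60.2 CPM in the fl/fl library (intervals 67.9 to 75.2 and 56.9 to 63.6) and 5.17 and 5.71 CPM in the Lyz2-cre library (4.38 to 6.06 and 4.88 to 6.65). The adrenergic receptor gene Adra2a was at 165 and 16.6 CPM, and Sox4 and Hes1, transcription factors of progenitor cells, were higher in the Lyz2-cre library, at 832 and 198 CPM against 396 and 110 CPM. At 1 h Csf1 was at 151 CPM in the fl/fl and 56.1 CPM in the Lyz2-cre library and Hsph1 at 57.9 and 17.4 CPM. In naive brain Tnf was at 91.4 and 43.4 CPM and the class I gene H2-D1 at 978 and 506 CPM. In monocyte-like cells Ccl4 at 1 h was at 271 and 56.3 CPM, and in neutrophil-like cells at 3 h Il1rn was at 279 CPM in the fl/fl and 817 CPM in the Lyz2-cre library. These differences exceed counting error, and with no second library they have no replicate check. Many other genes met the same bounds of level and intervals. In microglia-like cells 721 were higher in fl/fl and 1407 in Lyz2-cre at 3 h, 832 and 639 at 1 h, and 385 and 796 in naive brain. The counts were 248 and 272 in monocyte-like cells at 1 h and 334 and 472 in neutrophil-like cells at 3 h.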

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

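The tests of tissue handling and of marrow were chosen after the cluster and list patterns had been seen and before the values that decide them were computed. The splits of the libraries were planned before the data were examined.

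From naive brain to 1 h the microglia-like share moved by 5.03 percentage points in fl/fl and by -5.01 percentage points in Lyz2-cre mice, opposite directions that differ by -10.0 percentage points. The Lyz2-cre minus fl/fl difference in that share changed sign between 1 h and 3 h, a move of 16.8 percentage points. For neutrophil-like cells the same difference changed sign between 1 h and 3 h, a move of -11.5 percentage points, and between naive brain and 3 h, a move of -7.26 percentage points. None of these differences was tested, since each rests on 1 library per group. Cells that took no class name were a signal outside the comparisons: cluster 19, led by haemoglobin genes with the division genes Top2a and Mki67, made up 1.40% of the Lyz2-cre 1 h library and at most 0.686% of any other. Cluster 22, led by Elane, Prtn3 and Mpo, genes of neutrophil precursors, made up 1.54% of that library and at most 0.386% of any other.

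With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. In microglia-like cells the genotype split gave 61 genes and the highest other split 57, and 1 of the 10 splits gave as many. In monocyte-like cells the genotype split gave 4 genes and the highest other 20, and 10 of the 10 splits gave as many. In neutrophil-like cells the genotype split gave 2 genes and the highest other 99, and 4 of the 10 splits gave as many. With time in the model, splits that compare 1 time alone come in pairs that make the same test, so fewer than 10 comparisons are distinct. Each split other than the genotype split also still sets the genotypes against each other at 1 time or more. The splits with 99 genes, for example, compare the 1 h libraries alone. These splits therefore do not show what grouping without regard to genotype would give.

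In Lyz2-cre microglia-like cells 4 of 20 immediate early, 4 of 15 chaperone and 4 of 13 chemokine genes fell, and over the immediate early and chaperone lists the median log2 ratio was -0.41 as the mean of the 3 times. If handling acted on every cell of a preparation, lymphocyte-like cells, which are not of the myeloid lineage, may show the shift too, although Lyz2 was at 461 CPM in NK-like cells of fl/fl naive brain and at 173 CPM in B-cell-like cells of the fl/fl 1 h library, so these classes are not shown to be free of myeloid transcripts. The middle of the 3 values was -0.11, between the bounds set beforehand of -0.2 for handling and -0.1 against it, with NK-like cells past the first at -0.28 and T-cell-like and B-cell-like cells between them at -0.11 each. Handling and genotype cannot be told apart here, since each preparation has 1 genotype and the bounds ask for 2 of the 3 classes, and chemokine genes were not part of the test. Loss of CD300a, loss of Lyz2 and the presence of Cre differ together between the genotypes and stay open as untested.

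Immediate early genes were lower after occlusion in microglia-like cells, with a median log2 change of the list of -1.40 at 1 h and -0.53 at 3 h. A candidate explanation is a difference in handling between naive and operated brains, since such genes also answer to tissue dissociation. At 3 h the middle of the 3 lymphocyte-like values was -0.45 (T-cell-like -0.45, NK-like -0.41, B-cell-like -0.55), with T-cell-like and NK-like cells short of the bound of -0.5 and B-cell-like cells past it, and neutrophil-like cells were at 0.57. At 1 h the lymphocyte-like values were -0.14, -0.11 and -0.39. Handling cannot be told apart from the occlusion, which every operated brain had and, if the titles' word naive holds, no naive brain had.

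Cells of immature type were more frequent in the Lyz2-cre 1 h library, where cluster 16 of immature neutrophils made up 5.02% of cells against at most 2.23% elsewhere. Bone marrow carried into the preparation could bring such cells, and B-cell precursors with them. Transcripts of 5 precursor genes (Vpreb1, Vpreb3, Igll1, Rag1 and Dntt) in B-cell-like cells were at 450 CPM (410 to 494) in that library, 0.830 times the highest other, fl/fl naive at 542 CPM (462 to 632). That level met the bound set beforehand against marrow, but it tests nothing, because marrow would raise the precursor transcripts and the total of the class together. The same UMIs of B-cell-like cells were also scaled by all UMIs of the library, a measure added after the values were seen. On that scale they were at 9.53 CPM in the Lyz2-cre 1 h library and at most 4.43 CPM elsewhere. Precursor transcripts in other cells were not counted. The B-cell-like share was 3.29% in that library against at most 1.85% elsewhere. The scaled value depends on that share, so these values are not separate evidence, and marrow stays open.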

How the results depend on the processing

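The alternatives that take the largest cluster of a class alone, and all those for shares other than neutrophil-like and monocyte-like, were chosen after the data were seen. All others named here were planned. Over all 464 results that the naming rule gives or the text names, 24 of 3965 values under these alternatives turned direction, in 17 results, and 2 of the 24 values were of results past the threshold. The 131 results named in the text, a subset chosen after values were seen, hold 0 of the 24. With DESeq2 126 of 131 named results kept their side of the threshold, with doublets kept 126 of 131, with DESeq2 size factors 81 of 81, and with 1 library left out 676 of 786. With DESeq2, microglia-like cells had 2099 genes at 1 h and 129 for genotype, monocyte-like cells 118 at 1 h and 1268 at 3 h, and neutrophil-like cells 100 at 1 h and 1333 at 3 h. DESeq2 is another test, and the cause of the moves was not tested. For the microglia-like genotype comparison there were 234 genes with no filter on low counts and 1 in the model without time. Monocyte-like cells had 137 genes at 1 h with doublets kept. In the largest cluster alone monocyte-like cells had 92 genes at 1 h and 1519 at 3 h, and neutrophil-like cells 123 and 1078, with fewer cells summed. With an estimated correlation camera called 0 lists at 1 h, 0 at 3 h, 0 between 1 h and 3 h and 0 for genotype, against 12, 13, 7 and 13 with the preset, and fry called 7, 13, 8 and 2. The run with an estimated correlation has only the 2 residual degrees of freedom. Its counts therefore do not show that correlation between genes removes the list results. Neutrophil-like shares with doublets kept were 3.64% (fl/fl 1 h), 9.63% (Lyz2-cre 1 h), 14.7% (fl/fl 3 h) and 9.59% (Lyz2-cre 3 h), and under the strict cell filter 2.83%, 8.66% and, at Lyz2-cre 3 h, 9.26%. Monocyte-like shares with doublets kept were 4.002% and 9.13% in the Lyz2-cre 1 h and 3 h libraries. The strict cell filter gave the fl/fl naive, Lyz2-cre naive, fl/fl 1 h, Lyz2-cre 1 h, fl/fl 3 h and Lyz2-cre 3 h libraries microglia-like shares of 87.5%, 85.4%, 91.5%, 80.8%, 73.2% and 79.8%, T-cell-like shares of 3.95%, 1.40%, 1.11%, 0.620%, 1.503% and 0.380% and B-cell-like shares of 0.0805%, 0.152%, 0.366%, 1.30%, 0.310% and 0.231%. Plasmacytoid dendritic cell-like shares under that filter were 0.0161% and 0.0305% in naive brain, 0% and 0.117% at 1 h and, at Lyz2-cre 3 h, 0%. At resolution 0.5 no cluster was NK-like or plasmacytoid dendritic cell-like, T-cell-like shares in the same 6 libraries were 8.96%, 4.92%, 2.87%, 1.96%, 3.13% and 1.87%, and the conventional dendritic cell-like share at fl/fl 1 h was 0.344%. At resolution 2.0 the naive libraries had T-cell-like shares of 6.28% and 2.30% and NK-like shares of 2.68% and 2.62%.

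With each library left out in turn, microglia-like cells had 831 to 4684 genes at 1 h, 2867 to 5971 at 3 h, 3017 to 5942 between 1 h and 3 h and 11 to 210 for genotype. Monocyte-like cells had 148 to 630, 1037 to 2889 and, for genotype, 9 to 66. Neutrophil-like cells had 2 to 292, 776 to 2686 and, for genotype, 2 to 95. Where this leaves a time with 1 library, that library is assumed to vary like the others. In the genotype contrast that library adds nothing, because time is in the model. The replicate numbers pair no libraries, since each group has number 1 alone, and the genotype model holds time and so compares genotypes within the 3 times. Border-associated macrophage-like tests were not run, for too few cells.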

Other observations

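Conventional dendritic cell-like cells made up 0.610%, 0.561% and 1.00% of the fl/fl libraries in naive brain, at 1 h and at 3 h and 0.729%, 0.426% and 0.894% of the Lyz2-cre libraries. NK-like cells made up 1.62%, 0.688% and 0.887% of the fl/fl and 1.84%, 0.984% and 0.831% of the Lyz2-cre libraries. B-cell-like cells made up 0.922%, 1.85% and 1.80% of the fl/fl and 1.42%, 3.29% and 1.54% of the Lyz2-cre libraries, and under the strict cell filter 0.0805%, 0.366% and 0.310% and 0.152%, 1.30% and 0.231%. Plasmacytoid dendritic cell-like cells numbered 41 over the 6 libraries, of which 20 were in the Lyz2-cre 1 h library, where the strict cell filter left 10. These shares have 1 library each and no replicate.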
